A study of Mus musculus with 2 samples.

How the data were processed

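RNA abundance was measured in 2 libraries of mouse bone marrow-derived dendritic cells, 1 control and 1 treated with UNE-C1. Per the labels, the cells came from female C57BL/6 mice aged 7 weeks and were grown with 20 ng/ml GM-CSF, which was renewed on day 3, and immature cells were collected on day 6. The labels give 100 nM UNE-C1 for 24 h as the treatment. They do not say what the control culture received. Libraries were made from 500 ng of total RNA with a QuantSeq kit, which reads messenger RNA near its 3' end, per the labels' protocols, so that read number does not scale with transcript length. No molecular identifiers are named in the sources used here, so PCR copies of a molecule cannot be told from separate molecules.

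The deposited files hold whole-number read counts per gene symbol with no normalization; this unit was read from the values, since the count column carries only a number as its header, 1 for the control and 3 for the UNE-C1 library. Which file belongs to which sample was taken from GEO's own record. What the numbers stand for, and whether further libraries were made, is not given in the sources used here, and no other library was analysed here. The submitters' processing notes name Bowtie2, edgeR and the mm10 genome build, without versions and without saying which step each served. The counting tool, the gene annotation, the handling of multiply mapped reads and the strand setting are not given in the sources used here. Genes with near-identical copies (ribosomal proteins and their pseudogenes, Tgtp1 and Tgtp2, and families such as the Gbp, Oas and Ifit genes) are therefore uncertain. The Eno1 count, with 2 reads in each library beside 3234 and 8738 reads on its copy Eno1b, is an example. The low Gapdh count may be another, but reads on its copies were not examined. Each file holds 23282 entries. The 35 symbols that occur more than once (79 entries) were summed, which left 23238 symbols, and no symbol was blank. The control library held 14857198 reads and the UNE-C1 library 15975821. The ribosomal RNA precursor Rn45s took 5.21% of the control reads and 3.98% of the UNE-C1 reads, and the 10 most abundant genes together took 16.0% and 19.2%.

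Counts were turned into CPM (read counts scaled to library size, as edgeR computes it) with effective library sizes from TMM (edgeR 4.0.16, R 4.3.3). The TMM factors were 1.13 for the control and 0.888 for the UNE-C1 library. Fold changes are log2((CPM + 1)/(CPM + 1)), UNE-C1 over control, and understate the change of genes with few reads. Where a fold is given as "-fold", it is the plain CPM ratio with its exact (Clopper-Pearson, conditional binomial) 95% interval from the 2 read counts (scipy 1.17.1). These intervals cover counting error only. A count of 0 was taken to allow up to 3 reads in that library, and no fold is given for it, although such a gene is ranked by the log2 value above. Genes with 50 or more reads in at least 1 library (10469 of the 15848 genes with a read) were compared. The floor of 50 reads corresponds to 2.99 CPM in the control and 3.52 CPM in the UNE-C1 library.

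With 1 library per group there is no replicate error. No p-value was computed, no count model was fitted, and a difference between the libraries has no replicate check. Genes were counted and ranked by size on the log2(CPM + 1) scale, at least 2-fold higher or lower, so that a gene with few reads can have a plain ratio above 2 and not be counted. A total of 19 pathway lists and 9 lists of cell type markers were fixed before the data were examined, as were the count floor, the thresholds, the random-list procedure and the rule for named genes. Each list with 5 or more members past the floor was described by its median log2 fold change and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a test of the treatment. The aminoacyl-tRNA synthetase list was written with older and newer symbols for the same genes, of which the files hold the older.

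The genes named are those fixed by the rule: the 12 highest and the 12 lowest fold changes past the floor (leaving out predicted genes, clone names, small RNAs and pseudogenes), up to 4 members of each list with the largest change, the 5 most abundant genes of each library, and a fixed set of receptors, cytokines and reference genes that includes Tlr2, Cars and Actb. Of the genes that a list includes but the rule does not name, Trim30a, Isg15, Ciita, Il12a, Il23a, Tnfsf15, Il6ra, Csf1, Adm, Ppbp, Ccl9, Nfkb1, Nfkb2, Rel, Rela, Relb, Nfkbia, Nfkbib, Tnip1, Tnfaip3, Herpud1, Sdf2l1, Hsp90b1, Hspa5, Xbp1, Edem1, Slc2a1, Ldha, Hif1a, E2f1, Tpx2, S100a8, S100a9 and Col1a1 were chosen after their values were seen. Gene positions come from GENCODE M21 (GRCm38, the assembly also called mm10), in which 22159 of the symbols occurred exactly once. Some results are not reported here.

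The procedure was tested on simulated data drawn from the means and depths of these libraries, with 200 genes changed. Both simulated libraries carried counting error only, and the changed genes were taken from those with 200 or more reads in a library. The simulation checks the calculation and cannot show how often unchanged genes would differ between 2 cultures. Of 63 genes changed by 2 on the log2 scale, 100% were counted as at least 2-fold changed in the right direction, as were 100% of 69 genes changed by 4. Of 68 genes changed by exactly 1, 30.9% were. No unchanged gene was counted (0% of those among 10163 genes past the floor), and 95.8% of the counting intervals held the simulated ratio. Of 200 random lists of unchanged genes, 6% fell outside the central 95% range. Alternatives tried were total counts and DESeq2 1.42.0 size factors in place of TMM, no floor and a floor of 200 reads, pseudocounts of 0.1 and 5, thresholds of 1.5-fold and 3-fold, a requirement that the counting interval exclude 1, random lists without matching, means in place of medians, and, added after the data were seen, leaving out the 13 genes that were among the 10 most abundant of either library, and the 8-fold counts under the other scalings, floors and pseudocounts.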

Results

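The data consisted of 3'-end RNA sequencing counts from bone marrow-derived dendritic cells, antigen-presenting cells grown from mouse marrow with the cytokine GM-CSF. One library came from a control culture and 1 from a culture exposed to 100 nM UNE-C1 for 24 h. UNE-C1 is a domain of cysteinyl-tRNA synthetase, known from earlier work as a ligand of the Toll-like receptors TLR2 and TLR6. The comparison asks which signalling molecules its addition induced. The control library held 14857198 reads over 14940 genes and the UNE-C1 library 15975821 reads over 14768 genes. Each group had a single library, so every difference given here is a difference between 2 libraries, without replicates, and the intervals cover counting error only.

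Of 10469 genes past the count floor, 975 (9.31%) were at least 2-fold higher in the UNE-C1 library and 986 (9.42%) at least 2-fold lower. At 8-fold on the log2(CPM + 1) scale, 122 genes were higher and 37 lower (76.7% higher). These counts depend on the pseudocount, which holds back genes with few reads: they were 165 and 110 (60% higher) with a pseudocount of 0.1 and 76 and 3 with 5. With total counts they were 95 and 53 (64.2% higher). Among the 122, 25 were on an interferon list and 7 on the glycolysis and hypoxia list, and among the 37, 10 were on the cell cycle list. Most were on none of the lists: 75 of the 122 and 25 of the 37. The median gene had a log2 fold change of -0.00. With total counts in place of TMM the median moved to -0.33, 657 genes were at least 2-fold higher and 1693 lower, and the share of higher genes among those changed went from 49.7% to 28.0%. The medians of all 25 lists moved down with it, by -0.23 to -0.34. Fold changes are therefore best read against the median gene.

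**Figure D1:**
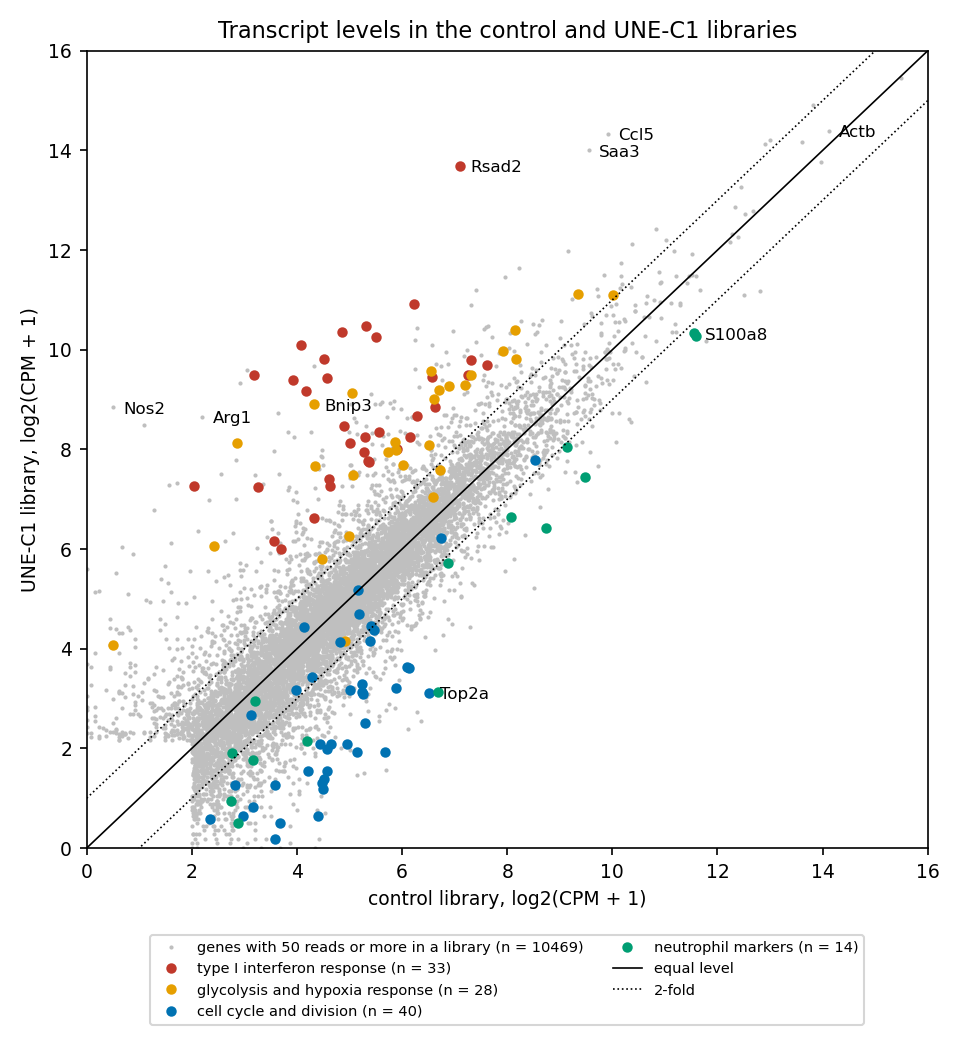
Level of each gene past the count floor in the control library (x axis) and the UNE-C1 library (y axis), both as log2(CPM + 1), with the solid line at equal level and dotted lines at 2-fold. The 33 type I interferon response genes lie above the upper dotted line, and 30 of 40 cell cycle genes and 12 of 14 neutrophil markers lie on or below the lower one.

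The gene with the highest fold change was Nos2, the inducible nitric oxide synthase, with 7 reads in the control and 6510 in the UNE-C1 library (log2 fold change 8.34; counting interval 532- to 2730-fold). Nos2 lies on chromosome 11 from 78920787 to 78960254 on the plus strand of GRCm38, the build of all positions given here. Arg1, the arginase that uses the same substrate, went from 3.59 to 400.3 CPM (112-fold, interval 86.6 to 146). The other 10 of the 12 highest were Iigp1, Rsad2, Ifit1bl1, Ms4a4c, Oasl1, Cmpk2, Tgtp1, Tgtp2, Cxcl9 and Ifit3, with log2 fold changes from 7.40 for Iigp1 to 5.48 for Ifit3. Tgtp1 and Tgtp2 are near-identical copies whose reads could have been split between them. Rsad2, which encodes the antiviral protein viperin (chromosome 12, 26442746 to 26456452), went from 136 to 13265 CPM and made up 1.18% of all UNE-C1 reads.

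Interferon-stimulated genes were higher as a group. All 33 measured members of the type I interferon list were at least 2-fold higher, from a log2 fold change of 2.08 for Trim30a to 6.59 for Rsad2, with a median of 2.87. The central 95% of random lists had medians of -0.09 to 0.39. Irf7, the transcription factor that amplifies interferon production, went from 38.8 to 1424 CPM (36.7-fold, interval 34.0 to 39.8), and Isg15, a ubiquitin-like modifier, had a log2 fold change of 4.69. Of 17 genes on the list of interferon gamma inducible GTPases and targets, 16 were at least 2-fold higher, with a median of 3.52 against -0.25 to 0.41 for random lists. Its largest values were those of Iigp1 (1.14 to 359 CPM), Tgtp1, the T cell-attracting chemokine Cxcl9 (24 and 1541 reads) and Gbp4 (log2 fold change 4.66). Ciita, the regulator of MHC class II genes, was the exception at 0.38.

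Cytokine transcripts were mostly higher. Of 18 measured cytokines and receptors, 11 were at least 2-fold higher and none 2-fold lower (median 1.80, random lists -0.31 to 0.35). Without the count floor the median over 24 members was 0.97. Il6, a pleiotropic inflammatory cytokine, had 6 and 226 reads (44.4-fold, interval 20.1 to 122). Il12b, the shared p40 subunit of IL-12 and IL-23, went from 169 to 1147 CPM (6.79-fold, interval 6.52 to 7.07). The partner subunits Il12a (0 and 6 reads) and Il23a (2 and 1 reads) were below the floor. Il1b was 5.57-fold higher (interval 5.24 to 5.94), and Il15 6.37-fold higher (5.61 to 7.25). Il10, an anti-inflammatory cytokine, had only 2 and 69 reads, and its ratio of 40.7 has an interval of 10.8 to 343. The 4 members below 0 were Tnfsf15, Il6ra, Tnf and Csf1, with log2 fold changes of -0.70, -0.36, -0.32 and -0.13. Tnf was at 37.5 CPM in the control and 29.8 CPM in the UNE-C1 library, 1.26-fold lower (interval 1.11 to 1.43). Of 21 chemokines, 12 were at least 2-fold higher and 2 at least 2-fold lower (median 1.59, random lists -0.32 to 0.38). The median was 0.96 with a pseudocount of 5 and 1.003 with a floor of 200 reads. Ccl5, which attracts T cells and monocytes (chromosome 11, 83525778 to 83530518), went from 960 to 20692 CPM and took 1.84% of all UNE-C1 reads. Cxcl10 was 35.8-fold higher (interval 29.4 to 43.9). Cxcl11, counted among the 12, had 6 and 289 reads and is annotated as a polymorphic pseudogene in GENCODE M21. The 2 lower chemokines were Ppbp and Ccl9, with log2 fold changes of -2.57 and -1.81.

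**Figure D2:**
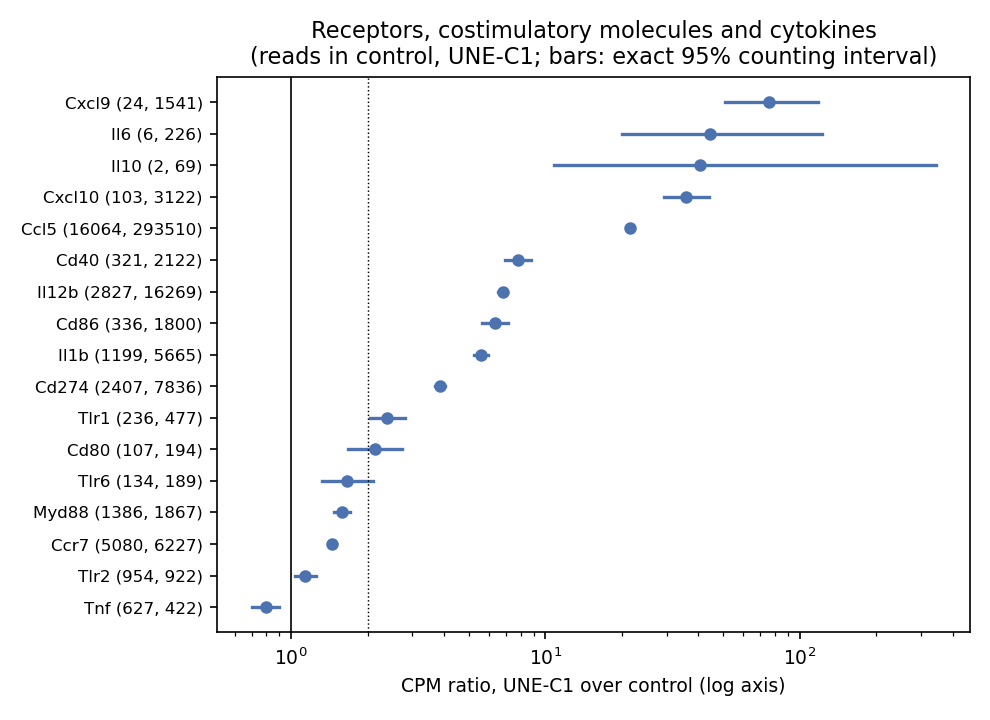
CPM ratio of UNE-C1 over control on a log axis for 17 receptors, costimulatory molecules and cytokines; points are ratios, bars exact 95% counting intervals, and the numbers beside each name the reads in the control and UNE-C1 libraries. Tnf lies below 1 and Tlr2 at 1.14, while Cxcl9, Il6 and Il10 lie furthest right, with wide intervals from few control reads.

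Among dendritic cell maturation genes, 9 of 22 were at least 2-fold higher and none 2-fold lower (median 0.71, mean 1.08, random lists -0.23 to 0.41). Cd40, the receptor for T cell help (chromosome 2, 165055627 to 165072948), went from 19.2 to 150 CPM (7.80-fold, interval 6.93 to 8.80). Cd86, which costimulates T cells through CD28, was 6.32-fold higher (5.62 to 7.12), and Tnfrsf9, which encodes 4-1BB, 7.70-fold higher (7.26 to 8.16). The ratio for Cd80 was 2.14 with an interval of 1.68 to 2.73. The inhibitory ligand Cd274, which encodes PD-L1, was 3.84-fold higher (3.67 to 4.02). Ccr7, the receptor for migration to lymph nodes, was already at 304 CPM in the control and had a log2 fold change of 0.53. Of 18 genes of MHC class I presentation, 11 were at least 2-fold higher (median 1.24, random lists -0.20 to 0.53). They included the peptide transporter Tap1 (5.56-fold, 5.23 to 5.92), H2-K1 (3.36-fold, 3.31 to 3.41), Tapbp and Psmb9. None of the 12 genes of MHC class II presentation was counted as changed 2-fold on the log2(CPM + 1) scale, and their median of -0.00, which turned positive with DESeq2 size factors, was at percentile 34.7 of random lists. H2-Ab1 was at 2732 CPM in the control and 2594 CPM in the UNE-C1 library, and Ctss, which trims the invariant chain, was 1.75-fold higher (1.74 to 1.77). H2-Ob, on 36 and 63 reads, had a ratio of 2.06 (1.35 to 3.20) and a log2 fold change of 0.79, and H2-Oa a log2 fold change of 0.62.

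For the receptors of UNE-C1 itself, Tlr2 (chromosome 3, 83836272 to 83841767) had 954 and 922 reads, a ratio of 1.14 (interval 1.04 to 1.25) that turned below 1 with total counts. Tlr6 had 134 and 189 reads (1.66-fold, 1.33 to 2.09). Tlr1, not named above as a receptor of UNE-C1, had 236 and 477 reads (2.38-fold, 2.04 to 2.80), and the adaptor Myd88 was 1.59-fold higher (1.48 to 1.70). Of 28 Toll-like receptor signalling parts, 6 were at least 2-fold higher and 1 lower (median 0.58, random lists -0.18 to 0.33). The higher ones included Irf7, the double-stranded RNA receptor Tlr3 (4.36-fold, 3.51 to 5.46) and the ubiquitin ligase Traf6 (2.54-fold, 2.19 to 2.95), and the lower one was the scavenger receptor Cd36 (2.33-fold lower, 2.25 to 2.42). On a list of 29 NF-kappaB subunits, feedback inhibitors and target genes, 12 were at least 2-fold higher (median 0.81, mean 1.37, random lists -0.16 to 0.38). Besides Nos2 these included Saa3, an acute-phase protein (749 to 16374 CPM), Irg1, which makes itaconate (249 to 2835 CPM), and Ptgs2, the inducible cyclooxygenase (15 and 245 reads). No NF-kappaB subunit was among the 12. The subunits Nfkb1, Relb, Rela, Nfkb2 and Rel had log2 fold changes of -0.00, 0.26, 0.50, 0.80 and 0.84. Of the inhibitors, Tnfaip3 stood at -0.13 and Nfkbia at 0.81, while Nfkbib and Tnip1 were among the 12, at 1.45 and 1.04. Of the 29 genes, 23 were above 0 and 6 below.

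Transcripts of glycolysis and the hypoxia response were higher. Of 28 genes, 25 were at least 2-fold higher (median 2.19, random lists -0.12 to 0.41). The hypoxia-inducible genes Egln3 (44.4-fold, 36.6 to 54.5), Bnip3 (25.2-fold, 22.5 to 28.3), Ero1l (log2 fold change 4.08) and Ankrd37 (15.2-fold, 11.9 to 19.5) had the highest log2 fold changes of the list. Adm, on 7 and 224 reads, had a plain ratio of 37.7 and a log2 fold change of 3.57. The glucose transporter Slc2a1 and lactate dehydrogenase Ldha had log2 fold changes of 2.38 and 2.25. Hif1a itself stood at 0.45. Gapdh was 3.21-fold higher (2.99 to 3.45), a value left uncertain by its many copies. Of 44 oxidative phosphorylation genes, none changed 2-fold. Their median of -0.19 was at percentile 0.11 of random lists matched on expression, but at 5.27 without matching and at 12.2 with matching on transcript length. Ndufs8, Sdhd, Ndufb7 and Ndufb10 were lowest, from -0.61 to -0.53. Of 21 NRF2 targets and metallothioneins, 9 were at least 2-fold higher (median 0.70, random lists -0.20 to 0.51). Heme oxygenase Hmox1 was 10.7-fold higher (10.2 to 11.2), Mt2 5.86-fold (5.65 to 6.07), Gstm1 4.26-fold (4.11 to 4.41) and Gclc 3.95-fold (3.65 to 4.27). On the list of ATF4 and unfolded protein response targets 6 of 23 were higher and 3 lower, and the median of 0.37 was at percentile 96.7, or 99.05 without matching on expression. The median was 0.11 with a floor of 200 reads. The stress genes Trib3 (12 and 295 reads), Ddit4 (log2 fold change 3.36) and Ddit3 (3.74-fold, 3.47 to 4.03) were higher, while Psat1, an enzyme of serine synthesis, was 4.45-fold lower (3.54 to 5.63). Herpud1 and Sdf2l1 were also at least 2-fold lower, with log2 fold changes of -1.32 and -1.20. Of other unfolded protein response genes, Hsp90b1 and Hspa5 stood at -0.79 and -0.25, and Xbp1 and Edem1 at 0.38 and 0.44. Of the 23 genes, 12 were above 0 and 11 below.

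Cell division transcripts were lower. Of 40 cell cycle genes, 30 were at least 2-fold lower and none 2-fold higher (median -2.34, random lists -0.34 to 0.14). Rrm2, a subunit of ribonucleotide reductase, had 336 and 8 reads (35.6-fold lower, 17.9 to 83.1), Top2a 1518 and 109 (11.8-fold lower, 9.72 to 14.5), Stmn1 834 and 40, and the cyclin Ccnb2 185 and 2 (78.4-fold lower, 21.4 to 652). E2f1 and Tpx2, at 0.01 and 0.30, were the members above 0, and both turned below 0 with total counts. In the same library 12 of 14 neutrophil markers were at least 2-fold lower, with a list median of -1.42. Of 52 ribosomal protein genes, 7 were at least 2-fold lower and 50 were below 0 (median -0.71, random lists -0.03 to 0.39). Rpl3 (3.16-fold lower, 2.94 to 3.40), Rpl10a, Rpl4 and Rpl14 had the largest differences, and reads of this family are shared with pseudogenes. Of 28 genes of cholesterol and fatty acid synthesis, 7 were at least 2-fold lower and 1 higher (median -0.67, random lists -0.24 to 0.27). Fatty acid synthase Fasn was 4.70-fold lower (3.94 to 5.63) and Dhcr7 3.40-fold (2.56 to 4.58), and the exception was Pmvk, phosphomevalonate kinase, at 3.20-fold higher (2.86 to 3.59). Of 23 genes of cytosolic aminoacyl-tRNA synthetases and their partners, 3 were lower (Eef1e1, Vars and Iars) and 1, Mars, higher (3.05-fold, 2.82 to 3.29). The list's median of -0.10 was at percentile 12.2. Cars, the mouse gene for the enzyme that UNE-C1 derives from (chromosome 7, 143557230 to 143600090), had 218 and 311 reads (1.68-fold higher, 1.41 to 2.01).

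The 12 lowest fold changes belonged to Ppp1r1a, Nes, Galnt9, Ocstamp, Clec4b1, Adgre4, Clec1a, Rrm2, Stmn1, Cck, Mamdc2 and Matk. Their log2 fold changes ran from -4.23 for Nes to -3.61 for Matk, leaving out Ppp1r1a and Cck, which had 0 reads in the UNE-C1 library. The ranking depends on the pseudocount. Ccnb2, at 78.4-fold lower by plain ratio, is not among the 12, though Clec4b1, at 16.6-fold, is. Ppp1r1a had 322 reads in the control and 0 in the UNE-C1 library, and Cck had 198 and 0, where 0 reads allows a level of up to 0.211 CPM. The C-type lectin Clec4b1 was 16.6-fold lower (13.0 to 21.4), the adhesion receptor Adgre4 20.6-fold (13.9 to 31.7) and Ocstamp, which acts in osteoclast fusion, 35.1-fold (18.3 to 77.4). On the lysosome and phagocytosis list 7 of 31 genes were higher and 4 lower (median 0.33, percentile 87.9), and the median turned to -0.0076 with total counts. Without matching on expression the percentile was 99.07. The mannose receptor Mrc1 was 13.7-fold lower (10.9 to 17.4). The Fc receptor Fcgr1 went from 33.0 to 397 CPM, the scavenger receptor Marco was 4.07-fold higher (3.82 to 4.33) and the protease Ctsc 3.61-fold (3.49 to 3.73). Of 9 growth factor receptors, Il4ra was 2.73-fold higher (2.59 to 2.89), Csf2ra, the alpha chain of the GM-CSF receptor, 2.40-fold lower (2.33 to 2.48) and Kit 3.30-fold lower (1.97 to 5.79). The list's median of -0.67 (mean -0.33) was at percentile 1.47, but with a floor of 200 reads, which 5 members passed, the median was 0.18 and the percentile 47.1.

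**Figure D3:**
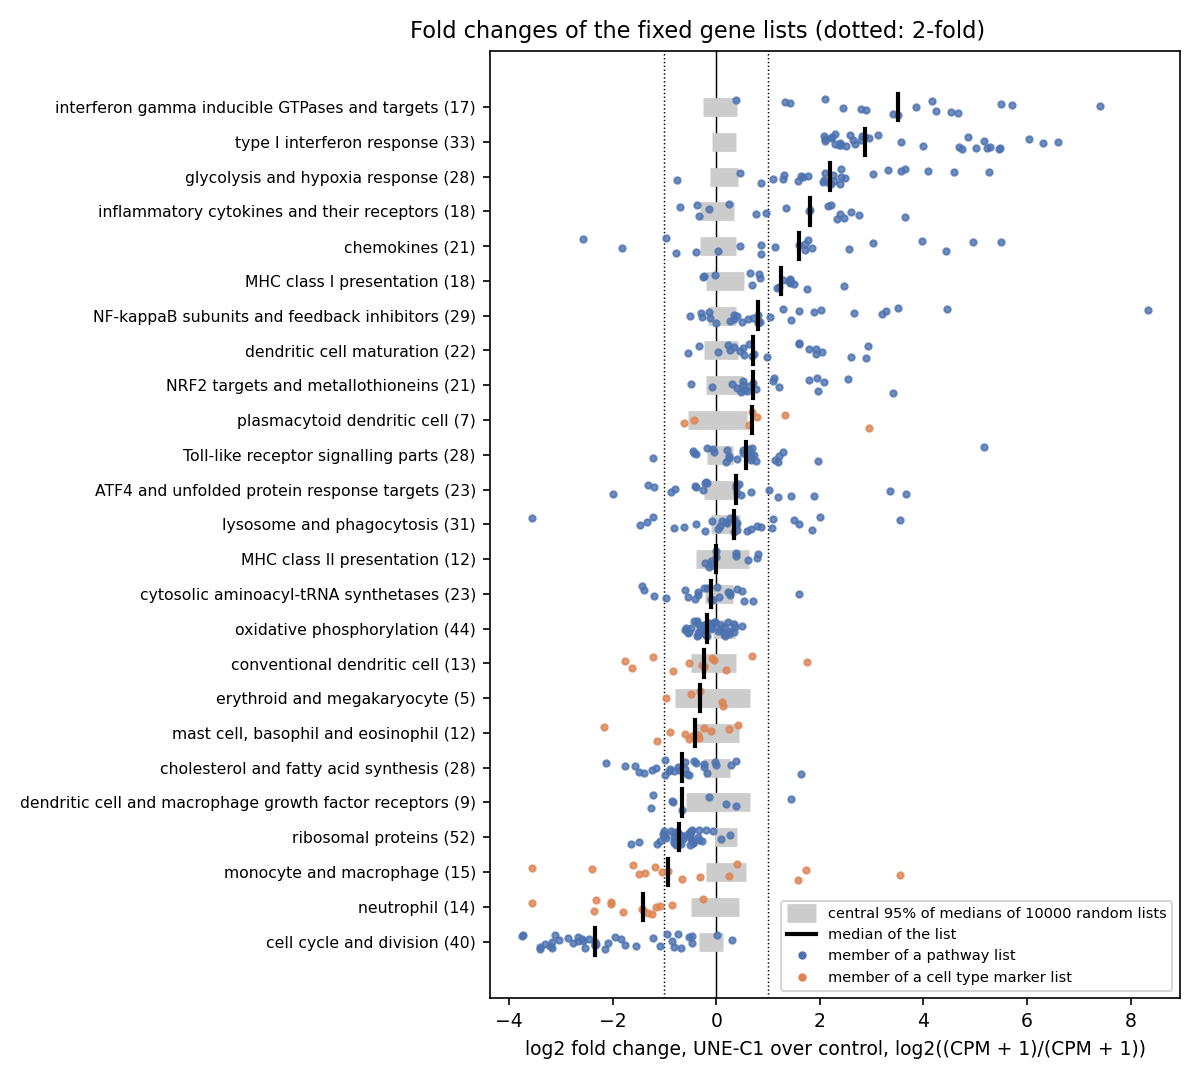
Log2 fold change (x axis) of every member past the count floor for the 25 lists with at least 5 such members, whose number is in brackets; points are genes, black bars list medians, grey bands the central 95% of medians of 10000 random lists matched on expression. The interferon lists stand highest, with medians of 3.52 and 2.87, and cell cycle and neutrophil markers lowest, at -2.34 and -1.42.

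Markers of the cell types that such a culture can hold did not move together. All 14 measured neutrophil markers were below 0 and 12 were at least 2-fold lower (median -1.42, random lists -0.48 to 0.45). S100a8 and S100a9 had log2 fold changes of -1.23 and -1.31, Retnlg had 1699 and 110 reads, and Elane had 106 and 6 reads. Mmp9 was 5.06-fold lower (4.76 to 5.38) and Mmp8 4.12-fold lower (3.94 to 4.30). Of 15 monocyte and macrophage markers, 7 were lower and 3 higher (median -0.93, mean -0.47, random lists -0.20 to 0.58). Mrc1 and Ccr2, the latter at 5.33-fold lower (4.91 to 5.80), stood against Fcgr1 and Ly6c2, the latter at 3.34-fold higher (3.24 to 3.44). Of 13 conventional dendritic cell markers, 3 were lower and 1 higher (median -0.24, percentile 16.4). Itgax, which encodes CD11c, was 3.08-fold lower (2.97 to 3.20) and Clec9a 4.36-fold lower (3.01 to 6.50), whereas Xcr1, on 54 and 189 reads, was 4.13-fold higher (3.04 to 5.70). Irf4 was 1.22-fold lower (1.07 to 1.39) and Irf8 higher, with a log2 fold change of 1.32.

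Of 12 mast cell, basophil and eosinophil markers, Siglecf and Cpa3 were at least 2-fold lower and the eosinophil granule protein Prg2 was 1.52-fold lower (1.49 to 1.56). Their median of -0.41 was at percentile 2.45, and inside the central range under 5 of the alternatives. Of 7 plasmacytoid dendritic cell markers, 2 were higher, Bst2 and Irf8, both of which are also on an interferon list (median 0.69, percentile 98.7). The 5 measured erythroid and megakaryocyte markers had a median of -0.31 (percentile 22.2), which turned to 0.09 with no floor, with Pf4 lowest at -0.97. B cell and T or natural killer cell markers were nearly absent, with 1 gene each past the floor, Cd22 (302 and 89 reads) and Klrd1 (76 and 9 reads). Of the stromal markers only Acta2, Tagln and Dcn passed it, and Dcn had 6 and 161 reads while Col1a1 had 6 and 8. The abundant reference transcript Actb was at 17775 and 21450 CPM, a ratio of 1.21 that turned below 1 with total counts. Fth1 and B2m, also among the 5 most abundant genes of the UNE-C1 library, were 2.13-fold (2.12 to 2.14) and 2.31-fold (2.29 to 2.32) higher. Of the remaining most abundant genes, Psap had a log2 fold change of 0.57, Tmsb4x was 1.15-fold lower (1.14 to 1.16) and Rn45s 1.03-fold lower (1.03 to 1.04).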

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

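Every value is limited by the single library per group. Depth limits the genes with few reads, whose intervals are wide. The requirement that the counting interval exclude 1 left the counts at 975 and 986, as the floor and the threshold together make it do. The list medians of interferon, glycolysis, cell cycle, ribosomal protein and neutrophil genes kept their direction under every alternative tried. With total counts, 657 genes were higher (all 657 among the 975) and 1693 lower (986 of them shared), since TMM and totals differ by one factor for all genes. With DESeq2 size factors the counts were 988 and 972, and with the most abundant genes left out, a test chosen after the data were seen, 994 and 1019. Fewer lower genes were counted with a floor of 200 reads (579, beside 776 higher) and a pseudocount of 5 (484, beside 724 higher), which raised the share of higher genes among those changed to 57.3% and 59.9%. Both settings act on genes with few reads. A 1.5-fold threshold gave 1904 higher and 2025 lower, and a 3-fold threshold 488 and 356. With total counts the list medians that moved beyond the 95% bootstrap interval over their members were those of dendritic cell maturation (0.37), MHC class II (-0.35), type I interferon (2.53), oxidative phosphorylation (-0.53), cholesterol and fatty acid synthesis (-0.98), ribosomal proteins (-1.05), aminoacyl-tRNA synthetases (-0.44), NRF2 targets (0.38) and lysosome (-0.0076, a change of sign). Of the lists within that interval, total counts moved Toll-like receptor parts to 0.24, NF-kappaB to 0.47, ATF4 targets to 0.04, growth factor receptors to -1.01, conventional dendritic cells to -0.58, mast cells, basophils and eosinophils to -0.73, plasmacytoid dendritic cells to 0.40 and erythroid markers to -0.64. The cell cycle median moved to -2.71 with a pseudocount of 0.1 and to -1.63 with 5. Without matching on expression, the percentile of oxidative phosphorylation was 5.27, inside the central range, and those of ATF4 targets and lysosome were 99.05 and 99.07, outside it. That of growth factor receptors was 47.1 with a floor of 200 reads, where 5 members passed. The cause of these shifts in percentile was not tested. The percentile of mast cell, basophil and eosinophil markers lay between 2.5 and 3.05 in 5 of its alternatives. Of the genes fixed by the naming rule, Tlr2, Actb and Hba-a1 turned sign, with total counts. The medians of MHC class II (with DESeq2 size factors and as a mean), growth factor receptors (floor of 200 reads) and erythroid markers (no floor) also changed sign. No paired analysis was possible because each group has 1 library.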

Other observations

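All genes and tests in this part were chosen after the results were seen, except the matching of ribosomal protein genes on transcript length. The values that come first are of single genes outside the fixed lists, and no gene family or pathway was tested with them. The arginine transporter Slc7a2 went from 77.3 to 1392 CPM, and Gch1, which makes a cofactor of nitric oxide synthase, from 67.0 to 204 CPM, while Ass1, which regenerates arginine, had only 9 and 17 reads and Arg2 a log2 fold change of -0.09. Slfn4, Slfn1 and Slfn8 had log2 fold changes of 5.10, 3.88 and 2.68, and Ms4a6d and Ms4a6c of 3.58 and 3.08. The complement factor Cfb went from 169 to 2341 CPM, while properdin, Cfp, was at 396 and 173 CPM.

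Lpl, lipoprotein lipase, went from 5834 to 2193 CPM, Mmp12 from 7149 to 2315 CPM, Fn1 from 361 to 36.1 CPM, and the lipid-sensing receptor Pparg had 226 and 16 reads. Fabp5, a fatty acid carrier, had a log2 fold change of 0.90. The beta-glucan receptor Clec7a had a log2 fold change of -1.71 and Clec4a2 -1.64. Clec4n, another lectin, stood at 0.27 and turned to -0.08 with total counts. Of 3 CD300 receptors, Cd300ld was at -2.86, Cd300lb at -1.78 and Cd300lf at 2.63. Ifnb1 had 0 and 1 reads and Ifng 0 and 2 reads, where 0 reads in the control allows a level of up to 0.179 CPM.

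Ribosomal protein genes were lower (median log2 fold change -0.71). A scale difference between the libraries would move genes of like level alike, and random lists matched on expression had medians of -0.03 to 0.39. That repeats the comparison given in the Results and is not a further test. It shows only that the list differs from genes of like level. For a bias against short transcripts the prediction was written beforehand. Random lists matched on length had medians from -0.27 to 0.17, which left ribosomal proteins at percentile 0. Length was that of the longest annotated transcript of each gene, with a median of 1124 nt for this list. The transcripts expressed may be shorter, so this argues against the bias only for the lengths matched. Reads moved to pseudogenes would raise their counts, but the 7 ribosomal protein pseudogenes with -ps in their names had a median of -0.54 and ran from -1.38 to -0.31. This covers those 7 only, since pseudogenes under other names were not examined. A lower output of ribosomal protein mRNA, or a change in which cells were present, remains as a hypothesis and was not tested.

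Cell cycle genes were lower (median -2.34, outside the -0.34 to 0.14 of expression-matched random lists). That repeats the comparison given in the Results and is not a further test. A scale difference would shift the list and the random lists alike, so it cannot account for the gap between them. One candidate explanation is that neutrophil precursors, which divide, were fewer in the UNE-C1 culture, since Elane, Mpo and Prtn3 summed had 335 and 53 reads (ratio 0.187, 0.137 to 0.250). The abundant neutrophil markers S100a8 and S100a9 fell less, with log2 fold changes of -1.23 and -1.31 (ratios 0.425 and 0.402, above that interval). A loss of precursors alone would lower division genes no further than the precursor genes. Of the 40 division genes, 10 had intervals wholly below that of the sum, 19 below that of Prtn3 (ratio 0.299, 0.199 to 0.439) and 4 below that of Mpo, but 0 below that of Elane (ratio 0.0668, 0.0240 to 0.150). The 3 precursor genes thus give different answers, and a loss of precursors cannot be told apart from other causes here. Fewer dividing cells of other kinds, and slower division under the treatment, stay open and untested.

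Glycolysis and hypoxia genes were higher (median 2.19, outside the -0.12 to 0.41 of expression-matched random lists). Here too the comparison is that of the Results, and a scale difference would shift both sides of it alike. The 8 hypoxia-inducible genes Bnip3, Egln3, Ero1l, Adm, Ndrg1, P4ha1, Ankrd37 and Vegfa, which are not enzymes of glycolysis, had a median of 3.61, from 2.11 to 5.27. A difference in oxygen or crowding between the 2 cultures could give this pattern, and so could the treatment. They cannot be told apart here because each condition is a single culture.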
